A study of Homo sapiens with 6 samples.

How the data were processed

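RNA of 6 samples of the human lung adenocarcinoma line H1975 was profiled on Affymetrix arrays, 3 from osimertinib-tolerant and 3 from naive cells. Groups and numbers were taken from the sample titles. Per the labels' protocols, 250 ng of total RNA per sample was converted to biotin-labelled single-stranded DNA with a whole-transcriptome kit. The authors deposited 1 normalized value per probe and sample, which is on a log2 scale judging by its range (2.42 to 17.52) and is given to 2 decimals. The submitters' processing notes name Transcriptome Analysis Console. The background correction, normalization and summary method and the version are not given in the sources used here. A method that equalises arrays would hide a change in total RNA per cell, and the fold of a dim probe depends on the background correction. No detection calls, scanner files or scan dates were used here, so dim probes were not marked as undetected and scan batches were not tested. Values in the bottom quartile of an array (below 5.02 to 5.12) are named as such where a printed fold or log2 change of a single gene rests on them.

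Probes were named through the platform annotation, with symbols checked through the Entrez identifier against a RefSeq table of assembly GRCh38.p14. Of 21448 probes, 17709 had 1 symbol, 0 had several and 3739 had none. The unnamed probes were tested and counted but not described. For 20 genes with more than 1 probe, the probe with the highest mean over the 6 arrays stood for the gene. The genome build of the array design is not given in the sources used here, so no coordinates are reported.

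Tolerant and naive cells were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the deposited log2 values, with group as the only term, two-sided, no filter, and Benjamini-Hochberg adjustment over all 21448 probes. A probe passed at an adjusted p under 0.05, and large changes were those with a fold of at least 2. Every adjusted p of a gene comes from this fit unless another setting is named. A gene "rose" or "fell" where it passed. Errors are SD over 3 arrays or the SE of the limma coefficient. The median residual SD was 0.16 on the log2 scale. Pairs of arrays within a group shared 335 to 448 identical values of 21448, with an SD of their difference of 0.29 to 0.32, so no array was a copy of another. All columns of values belonged to the 6 samples.

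The genes named were the 12 largest rises and 12 largest falls among genes that passed with a fold of at least 2 and no overlap between the groups' arrays, EGFR and MKI67 whatever their result, and for each list up to 4 members with the largest change among those that passed, or the 2 with the smallest p where fewer than 2 passed. The text gives values for most of these. The 40 gene lists held 1014 entries, of which 917 were measured. They were tested on 1 probe per gene with camera at a preset correlation between genes of 0.01, adjusted over the 40 lists. The same test with an estimated correlation, and fry, were run beside it. The list adjustment over the list alone used the Benjamini-Hochberg method on the members' p-values. Lists for leukocytes, fibroblasts, endothelium and handling stress covered other cells and sample quality.

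The fit was tested on simulated data with independent normal errors and the probes' spreads as moderated by eBayes, which suits its own model. In 3-against-3 comparisons of 21448 probes, 200 of them changed, it recovered 17% of changes of 0.5 on the log2 scale. It recovered 88.5% of changes of 1 and 99.7% of changes of 2, with 4.9% false calls. In the data 6501 probes passed, and the adjustment is less strict where more probes change. On that account the rates may understate recovery in the data. In simulations on 17687 genes, camera found 10 of 10 lists of 25 genes shifted by 0.5 and called 1 of 200 unshifted lists. The genes were drawn independently, and 1 list per simulation was shifted. In the data 32.4% of genes passed, and the mitosis and histone lists had estimated correlations of 0.2. The count of unshifted lists called therefore does not measure false calls in the data.

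Alternatives were quantile normalization, centring on array medians, leaving out the lowest 30% of probes by mean, an intensity trend, robust eBayes, array weights, the replicate number as a block, the week number as a covariate, 1 probe per gene, limma's treat, camera on ranks and leaving out each array. Lists without shared genes, and a loess correction (span 0.3) of the log2 change on mean expression, were added after the data were seen.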

Results

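Gene expression was measured in H1975 cells, an established human lung adenocarcinoma line whose growth depends on mutant EGFR, the epidermal growth factor receptor. Osimertinib is an inhibitor of mutant EGFR, and the cells that outlive an exposure to it are called drug-tolerant. The series compared 3 samples of tolerant cells with 3 samples of naive cells grown without the drug. Tolerant cells were those alive on day 8 of culture in 0.5 µM osimertinib. No group was exposed briefly or released from the drug, so effects of the drug's presence cannot be told apart from traits of surviving cells. The sources used here do not state on which day, or at what cell density, the naive cells were collected. Total RNA of each sample was labelled with biotin and hybridised to 1 Affymetrix array, giving log2 expression values for 21448 probes, each of which stands for a transcript cluster. Of these probes, 17709 carried 1 gene symbol and covered 17687 genes, and 3739 carried none. Array medians lay between 7.71 and 7.77. The number of arrays limits the precision, and the median standard error (SE) of a log2 change was 0.13. Nothing in the labels says that the samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The labels also differ on timing, since the sample sources give 1, 2 and 3 weeks for the arrays numbered 1 to 3 of both groups, whereas the design and the treatment protocol give 1 week and day 8.

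The comparison asked how the transcriptome of cells that survived osimertinib differed from that of untreated cells. Tolerant cells had lower levels of genes driven by ERK signalling, of DNA replication genes and of a list of ribosome biogenesis genes and MYC targets. Targets of the stress factor ATF4 were higher. Lists of mitosis genes, such as BIRC5 and FOXM1, and of replication histones fell in 35 of 35 and 39 of 43 members. Camera gave them the smallest adjusted p of the 40 lists (1.7e-27 and 1.4e-22), but they did not pass with an estimated correlation (0.0782 and 0.0832). Single genes of the contractile cytoskeleton (CNN1, ACTA2), the collagen matrix (COL1A1) and complement (C1S, C3) rose at least 10-fold. The changes at single genes reached 135-fold upwards for KCNK15, from a low naive level of 5.76, and 24.1-fold downwards for TCN1. With limma, 6501 of the 21448 probes passed an adjusted p of 0.05, of which 3203 were higher and 3298 lower in tolerant cells. A change of at least 2-fold was met by 1683 of them, 878 higher and 805 lower. Counted as genes, 5734 of 17687 passed, 2860 higher and 2874 lower, and 1516 of them changed at least 2-fold. The 3 tolerant and 3 naive arrays did not overlap at 9401 probes, or 43.8%, against 10% by chance. Arrays of the same group correlated at 0.996 across probes and arrays of different groups at 0.98 to 0.982, where probes are not independent replicates. The first principal component held 75.5% of the variance and parted the groups. When limma's treat tested directly for a change above 2-fold, 693 probes passed in place of 1683.

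The largest rise was that of KCNK15, a potassium channel gene, from 5.76 ± 0.38 (SD, n = 3 arrays) in naive to 12.83 ± 0.17 in tolerant cells, a log2 change of 7.07 ± 0.20 (SE) and an adjusted p of 4.9e-06 by limma. Its naive values (5.62, 5.47 and 6.19) were low, though above the bottom quartile of their arrays, so its fold may also depend on the background. CNN1, which encodes the smooth muscle protein calponin, rose 88.2-fold, from 8.28 to 14.74. MAP2, a microtubule-associated protein best known from neurons, rose 43.5-fold. IGFBP5, a binding protein of insulin-like growth factors, rose 33.7-fold, and 2 of its 3 naive values lay in the bottom quartile of their arrays, so that its fold also depends on the background. CEMIP, which takes part in hyaluronan breakdown, rose 30.7-fold. BCAM, a laminin receptor, rose 29.7-fold to 15.07. The estrogen sulfotransferase SULT1E1 rose 29.4-fold from a naive level of 4.03, which lay in the bottom quartile of the probes, so that its fold rests on the unstated background correction. The complement protease C1S rose 29.1-fold and CLDN1, a tight junction claudin, 28.1-fold. ACTA2, which encodes smooth muscle actin, rose 27.3-fold, from 8.53 to 13.30. ROS1, a receptor tyrosine kinase, rose 26.9-fold, with 1 naive value in the bottom quartile, and the membrane protein gene SUSD2 rose 23.4-fold. Adjusted p-values of these 12 genes ran from 2.7e-06 to 9e-05, and in each the arrays of the groups did not overlap.

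The largest fall was that of TCN1, which encodes a cobalamin-binding protein and fell by 4.59 on the log2 scale (SE 0.17, adjusted p = 1e-05 by limma), from 11.30 to 6.71. IL1RAPL1, a synaptic member of the interleukin 1 receptor family, was 22.1-fold lower. EGR1, an immediate early transcription factor, was 19-fold lower, and FOSL1, a subunit of the AP-1 factor, 14.1-fold lower. ETV1, an ETS transcription factor, was 12.8-fold lower and the progestin receptor gene PAQR5 12.4-fold lower. HAS2, a hyaluronan synthase, was 12.2-fold lower. SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, was 12-fold lower and ended at 4.32, within the bottom quartile of the probes. ARHGEF39 was 10.8-fold lower, and GPAT3, an enzyme of triglyceride synthesis, 10-fold lower. The myosin gene MYH15 was 9.92-fold lower and the collagenase MMP13 9.71-fold lower. Adjusted p-values of these 12 genes ran from 2.7e-06 to 0.00011.

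**Figure D1:**
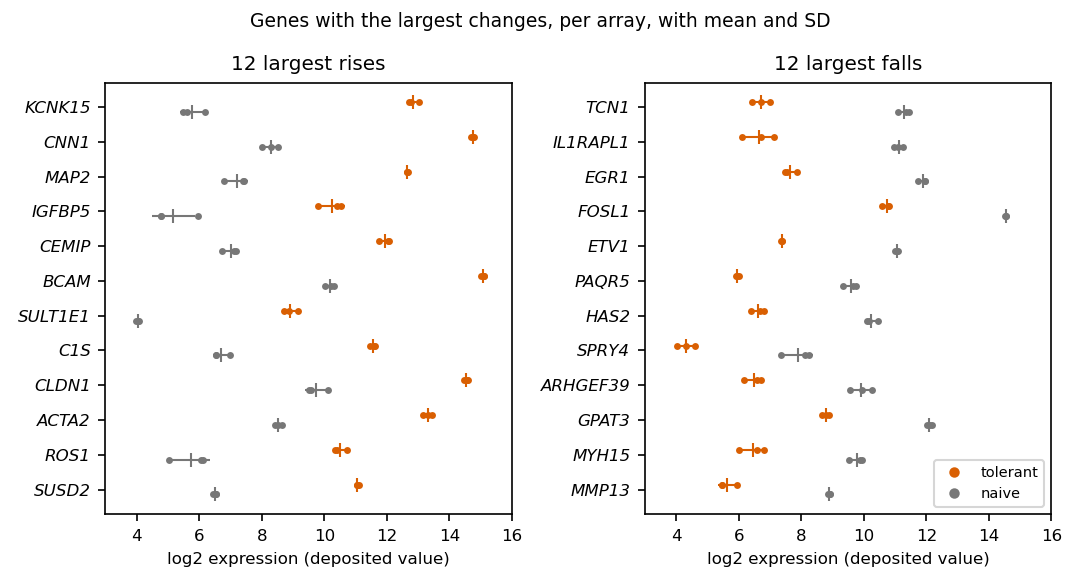
Log2 expression on each of the 6 arrays (horizontal axis, deposited values) for the 12 genes with the largest rises and the 12 with the largest falls, with points for arrays, a vertical tick for the mean of 3 arrays and a horizontal bar for the SD. Tolerant and naive points do not overlap in any of these genes, from KCNK15 at 12.83 against 5.76 to MMP13 at 5.62 against 8.90.

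Gene lists were tested with limma's camera, and 18 of the 40 passed, 10 higher and 8 lower. With an estimated correlation between genes, 4 of these calls held, namely ERK pathway output, DNA replication, ATF4 targets and ribosome biogenesis. That test was stricter even where the estimate lay below the preset 0.01. It rests on the 4 residual degrees of freedom of the fit, which the test with a preset correlation does not. The ERK list, at -0.02, went from an adjusted p of 8.3e-10 to 0.0488. Complement, also at -0.02, and cholesterol synthesis, at -0.05, lost their calls. Some other lost lists lay above 0.01, up to 0.2 for mitosis and histones. A lost call therefore does not by itself show correlation between the genes of a list. Where 5 or fewer members moved one way, they are named even if the naming rule did not choose them, and those were chosen after their values were seen.

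Genes switched on by ERK fell as a group. Of 23 measured members, 18 fell and 2 rose (19 and 3 adjusted over the list alone), with a median log2 change of -1.54 and an adjusted p of 8.3e-10 by camera. The call held at adjusted p = 0.0488 with an estimated correlation. EGR1, FOSL1, ETV1 and SPRY4, described above, fell the most, and the members that rose were EPHA4, an ephrin receptor, and SPRY1, a relative of SPRY4. SPRY1 lost its call without tolerant array 2 or 3 or naive array 1 or 2 (up to 0.062). EGFR itself, the target of osimertinib, fell 1.53-fold, from 12.04 to 11.43 (log2 change -0.61 ± 0.10 SE, adjusted p = 0.0039). Among EGFR family ligands, HBEGF rose 4.98-fold while EREG fell by 2.76 and TGFA by 1.56 on the log2 scale. That list of 9 had 2 rises and 3 falls, the same numbers adjusted over the list alone, and did not pass (adjusted p = 0.87). The other rise was EGF and the other fall NRG1. EGF's call (adjusted p = 0.041) was lost after median centring (0.054) and when any 1 of 5 arrays was left out, with adjusted p from 0.083 to 0.12 (0.0018 without tolerant array 1). Receptor tyrosine kinases moved in both directions, 7 of 25 up and 6 down (9 and 6 adjusted over the list alone), without passing as a list (adjusted p = 0.66). DDR2 and DDR1, receptors for collagen, rose 3.02-fold and 2.66-fold, AXL fell by 1.63 on the log2 scale, and KIT rose 2.60-fold from 3.64 to 5.02, within the bottom quartile of the probes.

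All 33 genes of DNA replication and the G1/S transition fell, also adjusted over the list alone, with a median log2 change of -1.43 (adjusted p = 7e-21 by camera, and adjusted p = 0.0488 with an estimated correlation). The replication licensing factor CDT1 was 6.88-fold lower, the helicase component CDC45 4.73-fold, the ribonucleotide reductase subunit RRM2 4.68-fold and GINS2 4.49-fold. All 35 genes of G2 and mitosis fell, also adjusted over the list alone, with a median of -1.82 (adjusted p = 1.7e-27). That list's test gave adjusted p = 0.0782 with an estimated correlation. BIRC5, which encodes survivin, was 9.47-fold lower, the mitotic transcription factor FOXM1 5.25-fold, the centromeric histone CENPA 5.23-fold and the kinase NEK2 5.10-fold. The proliferation marker MKI67 fell by 1.75 ± 0.11 (SE) on the log2 scale, 3.37-fold, yet remained at 12.30 (adjusted p = 6.2e-05). Among replication-dependent histones, 39 of 43 fell and H2AC6 alone rose (41 and 1 adjusted over the list alone), with a median of -1.63 and an adjusted p of 1.4e-22. The histone list had adjusted p = 0.0832 with an estimated correlation. H2BC14 was 6.85-fold lower and H1-5 6.11-fold lower, although histone genes resemble one another closely and their probes may share signal. H2AC6 lost its call without tolerant array 1 or 3 or naive array 1 or 3 (up to 0.067).

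The list of cyclin-dependent kinase inhibitors and genes linked to exit from the cell cycle was higher. Of its members, 15 of 26 rose and 3 fell (16 and 3 adjusted over the list alone), with a median log2 change of 0.49 and an adjusted p of 0.00047 by camera. This call was lost at adjusted p = 0.117 with an estimated correlation. PIK3IP1, a negative regulator of PI3 kinase, rose 10-fold, GAS6, a ligand of AXL, 6.84-fold, CCNG2, an atypical cyclin, 4.01-fold and MXI1, an antagonist of MYC, 3.68-fold. CCND3, KLF4 and RB1 fell. Of 9 genes with the symbol root CDKN, tested as a family after the results were seen, 3 rose and 3 fell (median log2 change 0.04, adjusted p = 0.99 by camera). Targets of p53 rose in 12 of 21 cases and fell in 5 (14 and 5 adjusted over the list alone), with a median of 0.43 (adjusted p = 0.032, and adjusted p = 0.214 with an estimated correlation). TP53INP1 rose 10.7-fold, TP53I3 3.23-fold and ZMAT3 3.04-fold, while AEN, BAX, DDB2, PLK3 and TNFRSF10A fell. The calls of 3 of these were not stable. Calls were lost for DDB2 without tolerant array 1 or 3 or naive array 2 or 3 (up to 0.078), for PLK3 without tolerant array 2 or 3 or naive array 1 or 2 (up to 0.08) and for TNFRSF10A without tolerant array 1, 2 or 3 or naive array 1 or 3 (up to 0.14). TNFRSF10A also lost it after quantile normalization (0.057), with the week number as a covariate (0.071) and, by a margin lost in rounding, with robust eBayes (0.05). On ranks, camera gave the p53 list an adjusted p of 0.056. The BCL2 family of apoptosis regulators had 1 rise, BMF, and 5 falls (2 and 6 adjusted over the list alone) among 16, and did not pass (adjusted p = 0.43). BAX was 1.54-fold lower and BCL2L1, which encodes the survival protein BCL-XL, 1.52-fold lower. The other falls were PMAIP1, BCL2A1 and BCL2L11. PMAIP1 lost its call without tolerant array 2 (adjusted p = 0.063) or 3 (0.054). BMF (adjusted p = 0.03) lost its call without tolerant array 3 (0.058), naive array 1 (0.066) or naive array 2 (0.087). BCL2A1 lost its call without tolerant array 2 or 3 or naive array 1, 2 or 3 (up to 0.12) and with an intensity trend (0.053).

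Genes of ribosome biogenesis and targets of MYC, tested as 1 list, fell. No member rose and 20 of 27 fell (21 adjusted over the list alone). The median log2 change was -0.53, with an adjusted p of 1.9e-08 by camera. The call held at adjusted p = 0.0495 with an estimated correlation. LYAR, a nucleolar protein, was 2.30-fold lower, TCOF1, a cofactor of ribosomal RNA transcription, 2.12-fold, MRTO4 2.01-fold and RRS1 1.98-fold. In oxidative phosphorylation, 21 of 40 members fell and none rose (22 and none adjusted over the list alone), with a median of -0.29 (adjusted p = 1.9e-06, and adjusted p = 0.0832 with an estimated correlation). NDUFS7 of complex I was 1.89-fold lower and CYC1, which encodes cytochrome c1, 1.83-fold lower. Of 20 glycolysis genes, 9 fell and none rose, the same numbers adjusted over the list alone, with a median of -0.29. The glycolysis list passed camera at 0.0031 and had adjusted p = 0.222 with an estimated correlation. PFKFB3, which sets the level of a phosphofructokinase activator, was 1.64-fold lower and TPI1 1.53-fold lower. Fatty acid oxidation genes included 8 falls and 2 rises, PPARA and HADHB, among 25, the same numbers adjusted over the list alone (adjusted p = 0.39). CPT1A, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, was 3.56-fold lower and the pyruvate dehydrogenase kinase PDK4 2.93-fold lower.

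In cholesterol synthesis, 11 of 20 members rose while EBP and HSD17B7 fell, the same numbers adjusted over the list alone, with a median log2 change of 0.41 and an adjusted p of 0.0083 by camera. Its test gave adjusted p = 0.117 with an estimated correlation. SREBF2, the transcription factor that controls the pathway, rose 2.32-fold, and the enzymes SC5D, MSMO1 and LSS rose 2.18-fold, 2.09-fold and 1.97-fold. Fatty acid synthesis genes split, with 8 of 18 up and 4 down (9 and 4 adjusted over the list alone), and did not pass (adjusted p = 0.36). The desaturase genes FADS3 and FADS2 rose 4.46-fold and 2.04-fold, while ACSL5, ELOVL6, AGPAT2 and FASN fell. Calls were lost for HSD17B7 without tolerant array 1 or 2 or naive array 1, 2 or 3 (up to 0.12) and for FASN without tolerant array 2 or 3 or naive array 1 or 2 (up to 0.093). HSD17B7 also lost it with array weights (0.051) and with the week number as a covariate (0.063).

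Lysosome and autophagy genes were higher, 20 of 30 up against 3 down (21 and 3 adjusted over the list alone), with a median log2 change of 0.52 and an adjusted p of 9.2e-06 by camera. The call was lost at adjusted p = 0.189 with an estimated correlation. GABARAPL1, which is conjugated to autophagosome membranes, rose 7.28-fold, the protease CTSF 3.40-fold, WIPI1 2.97-fold and the ceramidase ASAH1 2.41-fold, while GUSB, CTSL and GLA fell. GLA lost its call without tolerant array 1 or 3 or naive array 1, 2 or 3 (up to 0.086). Targets of ATF4, the factor of the integrated stress response, rose in 22 of 31 cases, and VEGFA and SHMT2 fell (24 and 2 adjusted over the list alone). The median was 0.66 (adjusted p = 3.1e-09), and the call held at adjusted p = 0.0495 with an estimated correlation. ALDH1L2, a mitochondrial folate enzyme, rose 7.24-fold, the glutathione-degrading CHAC1 5.34-fold, NUPR1 4.48-fold and ATF3 4.10-fold. The unfolded protein response list did not pass camera (adjusted p = 0.39), with 8 of 20 up and 4 down (9 and 4 adjusted over the list alone). The chaperone gene DNAJB9 rose 2.63-fold, and MANF, SDF2L1, PDIA4 and CRELD2 fell. SDF2L1 (adjusted p = 0.018) lost its call without naive array 2 (0.059) or 3 (0.054). CRELD2 lost its call without tolerant array 2 or 3 or naive array 1 or 3 (up to 0.093). Among 26 targets of the antioxidant factor NRF2, AKR1C3, TXNRD1 and AKR1C1 rose and 6 members fell (4 and 8 adjusted over the list alone), and the list did not pass (adjusted p = 0.45). HMOX1, heme oxygenase, was 4.98-fold lower and GCLM, a subunit of the enzyme that starts glutathione synthesis, 2.61-fold lower.

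In the mesenchymal list, 10 of 30 members rose and 5 fell, the same numbers adjusted over the list alone, and the list did not pass camera (adjusted p = 0.16). Besides ACTA2, TAGLN, a smooth muscle actin-binding protein, rose 13.1-fold, and the collagen I genes COL1A1 and COL1A2 rose 12.7-fold and 8.86-fold. AXL, SNAI1, MMP2, TNC and ITGA5 fell. Calls were lost for TNC without tolerant array 2 or 3 or naive array 2 (up to 0.091) and for ITGA5 without tolerant array 1, 2 or 3 or naive array 2 or 3 (up to 0.12) and after quantile normalization (0.054). Markers of fibroblasts, another cell type that makes these products, had 4 rises and no fall among 11, the same numbers adjusted over the list alone, with a median log2 change of 0.21. Camera gave that list an adjusted p of 0.039, and its test gave adjusted p = 0.201 with an estimated correlation. The 4 were COL1A1, COL1A2, MFAP4 and PDGFRB, and 6 of the 11 markers also stood in another list. In naive cells, 6 of the 11 already lay above the bottom quartile of the probes. Without genes shared between lists, a step chosen after the data were seen, the fibroblast list had an adjusted p of 0.56. That step took out COL1A1 and COL1A2, the largest rises of the list, so the loss was largely built in. The full list lost its call on ranks (0.12), after quantile normalization (0.057), after a correction for expression level (0.057) and without tolerant array 2 (0.072).

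Target genes of YAP and TEAD, which respond to cell shape and stiffness, rose in 12 of 22 cases and fell in 4 (13 and 4 adjusted over the list alone), with a median log2 change of 0.52 and an adjusted p of 0.0045 by camera. The call was lost at adjusted p = 0.111 with an estimated correlation. ANKRD1 rose 10.7-fold, CCN2 5.07-fold and IGFBP3 4.89-fold, while NT5E, a cell surface nucleotidase, was 9.23-fold lower, and AXL, SHCBP1 and AMOTL1 also fell. Genes of TGF-beta signalling rose in 13 of 22 cases (14 adjusted over the list alone), with a median of 0.68 (adjusted p = 0.001, and adjusted p = 0.239 with an estimated correlation). INHBA, an activin subunit, rose 14.6-fold, LTBP2 6.85-fold, the receptor TGFBR1 4.52-fold and THBS1 2.98-fold. The ligand TGFB1, ID1 and BMP4 were the 3 falls, over all probes and adjusted over the list alone. The gene sets for WNT and NOTCH signalling did not pass (adjusted p = 0.31 and 0.94). WNT had 6 of 27 up, with WNT7B and FZD4 down, and DKK3, a secreted protein of the dickkopf family, rose 4.65-fold from 4.95, within the bottom quartile of the probes. NOTCH had 4 of 24 up, namely MAML2, DTX4, NOTCH2 and JAG2, and HES1, HEY1 and NRARP down. In both lists the numbers were the same adjusted over the list alone. Calls were lost for WNT7B without tolerant array 1 or 2 or naive array 2 or 3 (up to 0.12), for JAG2 without any 1 of the 6 arrays (up to 0.13), after quantile normalization (0.051), after median centring (0.075) and with the week number as a covariate (0.067), for HEY1 without tolerant array 2 (up to 0.053) and for NRARP without tolerant array 1, 2 or 3 or naive array 3 (up to 0.064).

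Complement genes rose, 10 of 15 up with C5 and C1QBP down, the same numbers adjusted over the list alone. The median log2 change was 0.81 (adjusted p = 0.00029 by camera, and adjusted p = 0.0832 with an estimated correlation). Beside C1S, the proteases CFI and C1R rose by 4.13 and 3.22 on the log2 scale, and C3, the central component of the cascade, rose 10-fold to 15.51. Cytokine genes under NF-kappaB had 6 of 26 up and CXCL8, TNFAIP2 and NFKBIA down (8 and 4 adjusted over the list alone), without passing (adjusted p = 0.33). The chemokine gene CCL2 rose 5.88-fold and the adhesion molecule ICAM1 2.47-fold. Calls were lost for TNFAIP2 without tolerant array 1 or 3 or naive array 2 or 3 (up to 0.092) and for NFKBIA without tolerant array 1 or 3 or naive array 1 or 2 (up to 0.083). TNFAIP2 also lost it with the week number as a covariate, by a margin lost in rounding (0.05). Interferon response genes split, with 16 of 46 up and 15 down (19 and 16 adjusted over the list alone) and an adjusted p of 0.87. Their median of -0.10, mean of 0.01 and the upward direction of the test differed in sign. IFI27 and GBP2 rose 4.20-fold and 3.46-fold, while OASL and IFIT3 were 5.39-fold and 3.36-fold lower. In MHC class I presentation, 6 of 14 rose and PSMB9, TAP2 and PSMB8 fell, the same numbers adjusted over the list alone (adjusted p = 0.51). The peptidase ERAP1 rose 1.62-fold and HLA-E 1.48-fold. HLA-C rose 1.84-fold (adjusted p = 0.019), a call lost without tolerant array 1 (0.057), naive array 1 (0.057) or naive array 3 (0.06). HLA genes resemble one another, so that their probes may share signal. In MHC class II, HLA-DMA and HLA-DPA1 rose and CIITA, CTSS and HLA-DRA fell among 13, the same numbers adjusted over the list alone (adjusted p = 0.87). HLA-DRA (adjusted p = 0.036) lost its call without any 1 of 5 arrays, with adjusted p from 0.057 to 0.11 (0.0086 without naive array 3), and with the week number as a covariate (0.054). HLA-DPA1 lost its call without tolerant array 2 or 3 or naive array 1 or 2 (up to 0.081).

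Markers of alveolar type 2 cells, the surfactant-producing cells of the lung, rose in 9 of 20 cases and fell in 1, the same numbers adjusted over the list alone, with a median log2 change of 0.28. Camera gave an adjusted p of 0.011, and adjusted p = 0.117 with an estimated correlation. The mucin MUC1 rose 8.42-fold, the phosphate transporter SLC34A2 7.69-fold and the protease inhibitor SLPI 2.97-fold, and ETV5, which also stands in the ERK list, was 6.16-fold lower. Markers of alveolar type 1 cells did not pass (adjusted p = 0.87), with COL4A4, AKAP5 and HOPX up and EMP2, RTKN2 and VEGFA down among 15 (3 and 4 adjusted over the list alone). Their median of 0.07 and mean of 0.06 were positive while the test pointed down. HOPX lost its call without tolerant array 1 or 2 or naive array 1 or 3 (up to 0.092). Epithelial genes had 8 of 24 up and 5 down (9 and 5 adjusted over the list alone, adjusted p = 0.39). The tight junction gene OCLN rose 2.84-fold, and GRHL2, an epithelial transcription factor, OVOL2, PKP3, EPCAM and ESRP1 fell. OVOL2 (adjusted p = 0.026) lost its call without tolerant array 1 (0.079) or 3 (0.08) and without naive array 2 (0.062) or 3 (0.065). PKP3 lost its call without naive array 1 or 3 (up to 0.073). Stem cell and persister genes had 8 of 22 up and 6 down, the same numbers adjusted over the list alone (adjusted p = 0.58). NT5E, also in the YAP list, was 9.23-fold lower, while SOX4 rose 7.03-fold and CD24 3.64-fold. KLF4 was 2.37-fold lower and ended at 4.94, within the bottom quartile of the probes.

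Airway, neuroendocrine and squamous or mucinous markers did not pass as lists, with adjusted p of 0.22, 0.19 and 0.77. Among 16 cilium and airway markers KRT14, CIMAP3, DNAH5 and NGFR rose and TUBB4B fell, the same numbers adjusted over the list alone, and KRT14 moved from 3.43 to 4.94, within the bottom quartile of the probes. DNAH5 (adjusted p = 0.045) lost its call without any 1 of 5 arrays (0.077 to 0.13), but not without naive array 1 (0.011). It was also lost after quantile normalization (0.053) and median centring (0.057). NGFR (adjusted p = 0.029) lost its call without any 1 of the 6 arrays (0.056 to 0.097), after quantile normalization (0.054) and with an intensity trend (0.16). Of 14 neuroendocrine markers, SCG5, SCG2 and SEZ6 rose and ENO2 fell, the same numbers adjusted over the list alone, and SCG5 rose 3.80-fold. SCG2 (adjusted p = 0.014) had an adjusted p of 0.052 without tolerant array 2. Of 22 mucin and squamous genes, MUC16 rose 2.65-fold, KRT16 and S100A8 also rose, and CEACAM1 and CEACAM5 fell (1 and 2 adjusted over the list alone). KRT16 (adjusted p = 0.034) lost its call without tolerant array 1 (0.073) or 2 (0.06) and without naive array 2 (0.086) or 3 (0.1). S100A8 (adjusted p = 0.045) lost its call without any 1 of the 6 arrays (0.066 to 0.14). That call was also lost after quantile normalization (0.071), after median centring (0.08), with the week number as a covariate (0.07) and with an intensity trend (0.21).

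Markers of leukocytes and endothelium did not pass (adjusted p = 0.87 and 0.92). CD14 rose and CD68 and CD4 fell among 17 leukocyte markers, the same numbers adjusted over the list alone, and CD4 lost its call with an intensity trend (0.056). The median of 0.08 and mean of -0.02 of the leukocyte markers differed in sign. Of 12 endothelial markers, ESAM alone fell, over all probes and adjusted over the list alone, and KDR had a log2 change of 0.33 ± 0.11 (SE, adjusted p = 0.061) from a naive level of 4.94, within the bottom quartile. KDR passed without naive array 1 (0.022). Immediate early and heat shock genes, listed as signs of handling stress, fell in 8 of 17 cases while ATF3, JUND and HSPB1 rose (9 and 3 adjusted over the list alone), with a median log2 change of -0.33. Camera gave that list an adjusted p of 0.035, and adjusted p = 0.18 with an estimated correlation. EGR1, also an ERK target, led the falls, followed by IER5 at 2.16-fold and the chaperone HSPH1 at 2.05-fold lower. The list lost its call without naive array 2 (0.081) and without dim genes (0.063).

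**Figure D2:**
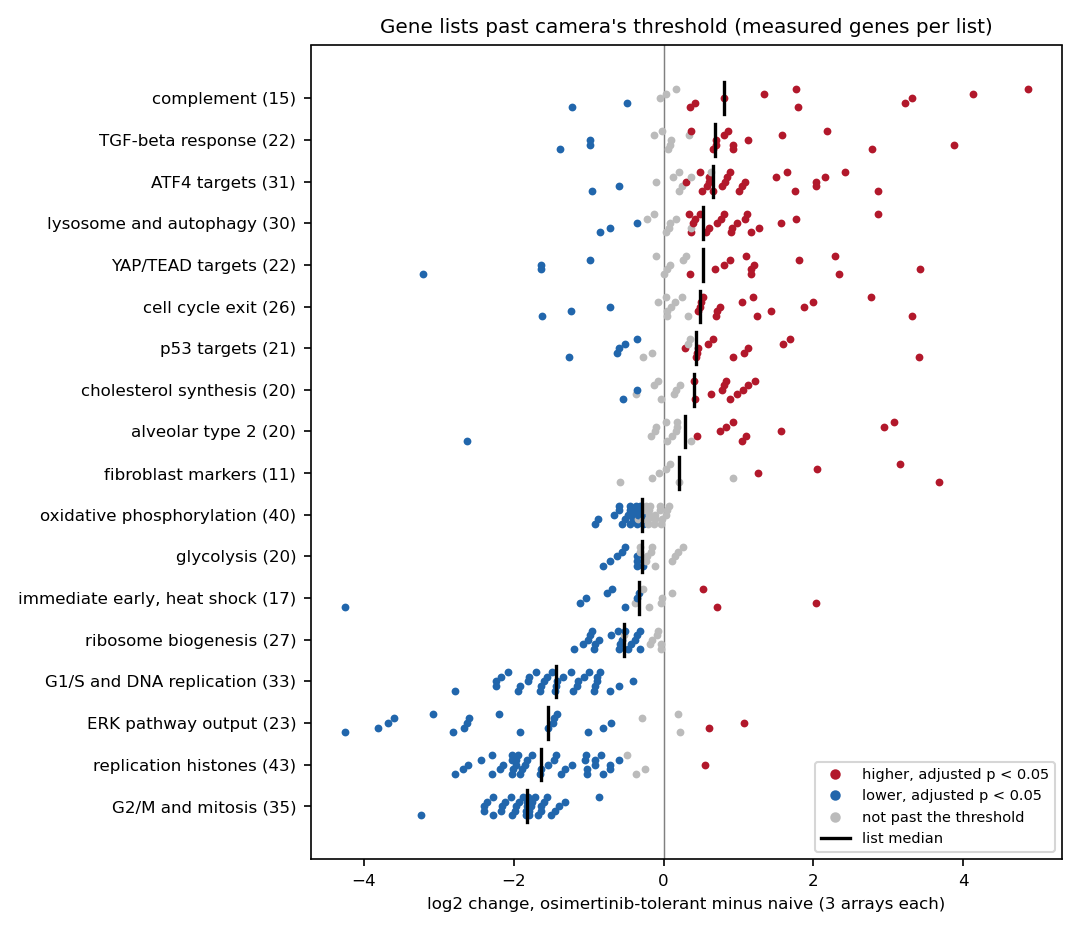
Log2 change between tolerant and naive cells (horizontal axis, 3 arrays each) of every measured member of the 18 lists that passed camera, with 1 point per gene, coloured by whether the gene passed an adjusted p of 0.05, and a black bar at the list median. Medians run from -1.82 for mitosis genes to 0.81 for complement genes.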

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

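The groups, lists, naming rule, tests and most alternatives were fixed before the data were examined; the tests without shared list genes and with a loess correction were chosen after. Across the planned settings, 5009 to 7623 probes passed, against 6501, and 1517 to 1725 with a fold of at least 2, against 1683, except that limma's treat passed 693, a stricter test by construction. Leaving out 1 array gave 5009 to 5557 and 1654 to 1725 probes. No probe was called with opposite signs. Centring moved the share of higher calls from 49.3% to 43.2%. Among calls with a fold of at least 2, the higher share moved from 52.2% to 48%, so the majority turned. Of the 40 lists, 18 passed, 4 with an estimated correlation and 32 with fry, which does not compare a list with other genes. Other settings passed 16 to 18.

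No pairing by replicate number was visible in the values. Deviations of same-numbered arrays correlated at 0.01, -0.02 and 0.01, and tolerant array 1 correlated best with naive array 2 (0.05). These correlations do not show how the samples were set up. With the replicate number as a block, 5496 probes passed, 1678 with a fold of at least 2, and 18 lists, and the interferon list reversed at an adjusted p of 0.99. Of the genes named by the rule, HLA-C (0.051), HLA-DRA (0.078) and EGF (0.057) lost their calls there. So did 16 genes named after their values were seen: HSD17B7 (0.1), S100A8 (0.11), TNFRSF10A (0.09), GLA, NFKBIA, TNC, RAB35, TNFAIP2, PKP3, PLK3, H2AC6, NGFR, JAG2, FASN, RAB8A and DDB2 (the others from 0.052 to 0.076).

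Lists that never passed camera reversed direction in some settings, and the cause was not tested. After quantile normalization and after the loess correction, NOTCH and endothelium reversed (0.98 each). Without dim genes, leukocytes (0.94) and endothelium (0.53) reversed, and without shared genes, alveolar type 1 and endothelium (0.9 each). Over arrays left out in turn, adjusted p ran from 0.69 to 0.98 for alveolar type 1, 0.8 to 0.95 for interferon, 0.71 to 0.98 for endothelium, 0.66 to 0.98 for MHC class II, 0.8 to 1 for NOTCH and 0.68 to 1 for leukocytes, each reversing at least once. Of 171 genes named by the rule, 170 passed, and 12 of these lost the call in some setting; of 66 named after their values were seen, 65 passed and 26 lost it. By setting, 6 of the named genes lost their calls after quantile normalization, 4 after median centring and 4 with an intensity trend. With the week number as a covariate 6 did, and with robust eBayes and array weights 1 each. Without dim probes 0 did, but that setting removed named genes such as CD4 and S100A8, which were not retested there. Apart from the block, each lost call is noted where the gene is named, except ELF3 (0.06 to 0.075 without tolerant array 1 or 2 or naive array 2 or 3). DCN, which did not pass, moved from 0.03 to -0.02 after quantile normalization and median centring, and from -0.06 to 0.10 over arrays left out. KDR passed with array weights (0.041). Signal over background was not measured, so folds of dim probes are uncertain.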

Other observations

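The gene families below and the tests of fibroblasts and of week numbers were chosen after the results were seen. Genes were grouped by the root of their symbol, and 43 of 628 families passed camera, 12 higher and 31 lower. None passed with an estimated correlation (adjusted p = 0.82 for each). That test gave the same value to families in which every measured member fell, such as CDCA and EXOSC, so it does not grade them. The families, chosen after the results were seen, are leads. No passing family changed the sign of its median after quantile normalization or median centring. Mitochondrial ribosomal proteins were lower, with 35 of 47 MRPL genes down and MRPL33 alone up (median log2 change -0.47, adjusted p = 2.7e-10) and 20 of 27 MRPS genes down (median -0.48, adjusted p = 7.4e-06). Nucleoporins fell in 17 of 20 cases (adjusted p = 3.7e-06) and all 9 measured EXOSC subunits of the RNA exosome fell (median -0.80, adjusted p = 0.00028), EXOSC8 by 1.32 on the log2 scale. MRPL33 lost its call without tolerant array 1, 2 or 3 (up to 0.063). Proteasome families were lower as well, with 9 of 12 PSMD genes and 8 of 11 PSMB genes down (adjusted p = 0.0044 and 0.0047).

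Of 16 clustered protocadherins of the beta group, 15 rose (median log2 change 1.07, adjusted p = 8.1e-07), PCDHB10 by 2.31 ± 0.12 (SE). Pregnancy-specific glycoproteins rose in 8 of 10 cases (median 1.39, adjusted p = 0.00039), while the 6 measured genes of the chorionic gonadotropin beta subunit all fell (median -2.69, adjusted p = 0.00016), although both are placental products. Members of these 3 families resemble one another and their probes may share signal, which was not tested. Alpha-mannosidases of glycan processing and of lysosomes rose in 8 of 9 cases (adjusted p = 0.00044). Of 71 RAB trafficking genes, 29 rose and RAB7B, RAB35 and RAB8A fell, with a median log2 change of 0.32 (adjusted p = 0.00091), and RAB7B fell by 1.65 on the log2 scale. Calls were lost for RAB35 without tolerant array 2 or 3 or naive array 1, 2 or 3 (up to 0.11) and for RAB8A without tolerant array 1 or 2 (up to 0.057). YPEL1, YPEL2, YPEL3 and YPEL5 rose among 5 genes of that family (adjusted p = 0.0093), YPEL2 by 2.64 ± 0.13 (SE). Glutathione transferases rose, all 5 GSTM genes and 4 of 5 GSTA genes (adjusted p = 0.0093 and 0.017), and these too resemble one another.

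Chance was examined by regrouping the 6 arrays into 3 and 3 in all 10 ways. The true split gave 6501 probes, 1683 probes with a fold of at least 2, and 18 lists, and the highest other counts were 0, 0 and 10. In each of the 3 counts 1 of the 10 splits, the true one, reached the observed number, and 10 splits cannot give a share under 0.1. Every other split sets 2 arrays of one group and 1 of the other against the rest, so part of the group difference stays in it.

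The rises of ACTA2, TAGLN, COL1A1 and COL1A2 raised the question of fibroblasts in the tolerant cultures, although neither the mesenchymal list (adjusted p = 0.16) nor the COL family of collagen genes (11 of 41 up, adjusted p = 0.065) passed camera. Fibroblasts would bring their other markers along, but the 9 fibroblast markers other than collagen I had a median log2 change of 0.09 (SD 0.83), against 3.67 ± 0.15 (SE) for COL1A1. Of the 9, MFAP4 rose by 2.05, from a naive level of 4.43 in the bottom quartile, and PDGFRB by 1.26 on the log2 scale. DCN, an abundant fibroblast transcript, had a log2 change of 0.03, with a sign that varied between settings. COL1A1 led this list, so a lower median among the other markers was built in, and MFAP4 and PDGFRB moved as admixture would. The median of 0.09 argues only against fibroblasts that carry most of these markers as the source of all 4 rises. A change of state within H1975 cells, or selection of cells that already had these levels, may account for them, and bulk RNA does not separate these.

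The numbers 1 to 3, which the source labels give as weeks, were tested for drift. Drift with the week would place arrays 1 and 3 farthest apart, but the share of the within-group sum of squares along that direction was 50.2% in tolerant and 49% in naive arrays, where 50% is the value without drift. With limma, 0 probes passed for the week number and 0 for its interaction with group, with 1218 (5.7%) and 1149 (5.4%) at an unadjusted p under 0.05. This argues against a steady drift large enough for these arrays to show, and which label is right stays open.

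The small falls of oxidative phosphorylation and glycolysis genes, which are highly expressed, could come from a trend of the log2 change with expression level. After a loess correction on mean expression, adjusted p was 1.5e-05 for oxidative phosphorylation (median -0.29 before and -0.26 after) and 0.0055 for glycolysis (-0.29 and -0.28), which argues against such a trend as the whole cause. Against 10000 random lists matched on expression, the medians stood at percentiles 0.03 and 0.69. The authors' normalization and correlation among the genes stay open. With an estimated correlation neither list passed (0.0832 and 0.222), but that test rests on 4 degrees of freedom, so the lost calls do not show correlation.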
